A study of Mus musculus with 2 samples.

How the data were processed

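Gene expression was measured on Affymetrix 3' expression arrays in cells sorted from the spleens of C57BL/6 mice that carried hepatocellular carcinoma, a liver cancer. Per the series' design text, 1 sample was sorted for Ter119, a surface marker of red cells and their precursors, and for lack of CD45, the common surface marker of white cells. The other sample consisted of CD45-positive cells from the same animals, and the labels do not say whether Ter119 was used in that gate. Each group had 1 array. Whether the RNA of several mice was pooled, and how many mice were used, is not given in the sources used here.

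The deposited table held 1 intensity per probe set and array on a linear scale. Per the labels' protocols, biotinylated cRNA was made from total RNA with a 3' in vitro transcription kit. The submitters' processing notes name GCRMA, a background correction and normalization method for such arrays, and the analysis program Partek 6.6, without saying which values each made. The deposited intensities ran from 0.5 to 104600 in the CD45-negative array and from 0.1 to 74470 in the CD45-positive array. Their means, with 2% of the values left out at each end, were 494 and 497. Such equal trimmed means are what scaling each array to a common level gives, and GCRMA values are by default on a log2 scale with equal distributions, which these were not. The step that made the deposited values is therefore not settled, and neither are detection calls or saturation, for which the table has no column.

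The table held 45037 probe sets and no control probe sets. GEO's platform annotation gave 34945 of them 1 gene symbol and 932 several, and 9160 were unnamed in it. Symbols were set against the RefSeq gene table of GRCm38.p6 by Entrez identifier, which held 34741 of the 34945 probe sets and changed 0 symbols. No coordinates are given, since no genome build goes with the array values. Intensities were converted to log2, with no pseudocount and no further normalization. Of several probe sets of a gene, the one with the highest mean log2 value of the 2 arrays stood for it, which left 18193 genes. Probe sets with several symbols or none took no part in the comparison.

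A gene counted as measured in an array when its intensity lay above 101.1 (log2 6.66). This level was the 95th percentile of 80 probe sets for olfactory and vomeronasal receptor genes over both arrays, which were taken as silent in spleen. In the CD45-negative array alone, that percentile was 127, and 195 of the genes at least 4-fold lower had a CD45-negative intensity between the common level and this one. For these only a lower bound holds. Counts and list medians use the common level as fixed, while bounds printed for single genes dim in the CD45-negative array are taken against 127, and those for genes dim in the CD45-positive array, whose own percentile was 73.5, against the common level. A value at or under the level was replaced by the level, so that the difference of a gene measured in only 1 array is a lower bound and is written "at least". Differences are log2 intensity in the CD45-negative array minus that in the CD45-positive array. Genes that differed by 4-fold or more (2 on the log2 scale) were counted. With 1 array per group there was no replicate and no residual degree of freedom, so the difference between the groups was not tested and no p-value is given. The arrays' number, 1 per group, limits the precision of every value. The only repeated measure was the agreement of different probe sets of a gene, whose pooled SD of the difference was 0.83 on the log2 scale over 5474 genes. It is not replicate error. Of these genes, 47 had probe sets that differed by 2-fold or more in opposite directions.

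The 29 gene lists, the detection level, the 4-fold threshold and the rule for named genes were fixed before the data were examined. A list's median difference was set against 10000 random lists of the same size, drawn from measured genes in 20 bins of mean intensity. The percentile describes these 2 libraries only. The rule for named genes took the 15 genes with the largest difference in each direction among genes measured in both arrays, the 10 brightest genes of each array among those not measured in the other, the 4 members of each list with the largest differences together with members that went 4-fold against their list, and Ptprc, Tfrc, Kit, Artn and Ly76, of which Ly76 had no value here. The text does not name every gene that the rule took, and a further gene of it is not reported here. Genes with clone or model names were passed over. Any further gene that the text names was chosen after its values were seen.

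Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data. The 2 simulated arrays had the real mean values, noise of SD 0.3 per array and 200 changed genes among 18193. They were drawn 20 times because a single draw held few changed genes of each size and fell short of the set recovery. Of the genes set lower by 3 on the log2 scale, 98.8% passed the 4-fold threshold, and of those set higher by 3, 99.5%. Of those set lower or higher by 1, 1% and 0.5% passed. The changed genes were drawn from genes whose mean lay more than 3 above the detection level on the log2 scale. The replacement of dim values by the level was therefore not tested. In the real arrays, 738 of the genes at least 4-fold lower and 151 of those at least 4-fold higher were such bounds. The noise was set and not estimated, so this recovery does not carry over to the real arrays. The alternatives were the mean of a gene's probe sets, 3 other detection levels (the 99th percentile of the receptor probe sets, a log2 value of 6, and none), quantile normalization, centring each array on its median over probe sets above the level in both, leaving out probe sets marked as cross-hybridizing, and 2-fold and 8-fold thresholds. A detection level set for each array was added after the data were seen, because the receptor probe sets were brighter in the CD45-negative array. Some genes stand in more than 1 list, such as Tfrc (haem and iron, housekeeping) and Ccl5 (cytotoxic cells, cytokines).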

Results

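RNA of 2 sorted cell samples from the spleens of mice with hepatocellular carcinoma was measured on 1 array each. The first held Ter119-positive, CD45-negative cells, referred to as CD45-negative cells. The second held CD45-positive cells, the white cell control. The design asks which genes set the CD45-negative cells apart from the CD45-positive cells of the same animals. Median intensity over all 45037 probe sets was 85.1 in the CD45-negative array and 87.8 in the CD45-positive array. Of 18193 genes, 9861 (54.2%) were above the detection level in the CD45-negative array and 10204 (56.1%) in the CD45-positive array. The receptor probe sets that set this level had a median intensity of 33.6 in the CD45-negative array and 17.5 in the CD45-positive array, so signal in probe sets taken as silent was not equal. There were no replicates, so no difference could be set against the spread between replicates. The error of the differences between the arrays could therefore not be estimated. The spread between probe sets of the same gene was 0.83 (SD, log2 scale), which is not replicate error.

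The CD45-negative cells were marked by very high levels of red cell genes and the CD45-positive cells by white cell genes. Of 11793 genes measured in at least 1 array, 8272 were measured in both, 980 were at least 4-fold higher and 1979 at least 4-fold lower in the CD45-negative array (1823 lower with a detection level set for each array, an alternative chosen after seeing the data). Among genes measured in both arrays, the largest difference was that of Tspo2, a gene of maturing erythroid cells, with an intensity of 19380 against 127.4, a difference of 7.25 on the log2 scale. Ank1, which encodes the red cell ankyrin, stood at 18418 against 145.6, and Rhd, an Rh blood group antigen, at 43882 against 402. The rest of the 15 highest, from 119-fold to 76.0-fold, were Ypel4, Fhdc1, Epb42, Dmtn, Ermap, Rab3il1, Kel, Specc1, Cdr2, Apol8 and Add2, of which Ermap and Kel encode blood group antigens. These values come from each gene's brightest probe set. With the mean of its probe sets, the difference was 1.70 for Rab3il1, under the 4-fold threshold, 4.40 for Ank1, 4.67 for Add2, 5.05 for Dmtn and 5.20 for Specc1. Hbb-b2, an adult beta globin gene, was 143-fold higher by its brighter probe set. Its other probe set gave a difference of -1.09, and both lie in a family of near-identical genes, so its value is uncertain.

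In the opposite direction, the 15 lowest genes included genes of lymphocytes, neutrophils and white cells at large. Ccl5, a chemokine of T and natural killer cells, had 121.3 in the CD45-negative array against 14904. Of the antibody variable genes, Igkv9-120 was 121-fold and Ighv14-2 112-fold lower, and Igkv6-14 stood at 102.6 against 9756, each of a family in which related genes share sequence. Ms4a4b was 115-fold lower, Gimap6, a GTPase of lymphocytes, 107-fold, and the cytotoxic protease Gzma 91.4-fold. Ms4a6b, Chil3, Bach2, Tgfbr2, H2-Ob, Cd22 and Mndal, with Ptprc, completed the 15 lowest, down to 69.9-fold for Mndal. The CD45-negative intensities of Ccl5, Igkv6-14, Bach2 and Tgfbr2 lay above the common level but not above 127, the 95th percentile of the receptor probe sets in that array, so only a lower bound holds for them. All lower bounds printed for genes dim in the CD45-negative array are taken against that percentile. The difference of Ccl5 was -6.87 or below, and Igkv6-14, Bach2 and Tgfbr2 were at least 76.7-fold, 63.9-fold and 59.4-fold lower. With the mean of a gene's probe sets, the difference was -2.39 for Tgfbr2, -3.88 for Igkv9-120, -4.04 for Ms4a4b, -4.19 for Bach2, -5.06 for Ptprc and -5.67 for Gimap6. Ptprc, which encodes CD45 itself and was the basis of the sort, had 422.7 against 32147 (76.1-fold lower), which checks the labels and is no finding. Its second probe set gave -1.80. Of the genes measured only in the CD45-negative array, the brightest was Tspan8, a tetraspanin, with 7005 (at least 69.3-fold higher). Mfsd2b, Samd11, Mylk3, Reep6, Ska1, Tinagl1, Slc22a23, Slc6a20a and Vangl1 followed, down to at least 38.8-fold for Vangl1. Averaged over probe sets, the difference was 2.54 for Ska1, 2.98 for Tspan8, 3.43 for Samd11, 3.82 for Vangl1 and 5.03 for Mfsd2b. The brightest measured only in the CD45-positive array were Ltb, a lymphocyte cytokine (at least 140-fold lower in the CD45-negative array), and the T cell receptor subunit Cd3d (at least 77.9-fold). Birc3, Cd2, Cd48, Arhgap30, Il16, Igkv15-103, Cd83 and Ptpn22 followed, down to at least 43.8-fold for Ptpn22. Averaged likewise, the difference was -2.42 for Il16, -3.74 for Birc3 and -4.20 for Arhgap30.

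Across all 11793 measured genes, log2 intensities of the arrays had a Pearson r of 0.59 and a Spearman rho of 0.56. These are correlations across genes, which are not independent replicates. Genes measured in both arrays had a median difference of -0.27. The median over all measured genes was -0.26 as deposited, 0.01 after quantile normalization and 0.18 after median centring. The excess of lower over higher genes depended on the scaling between arrays and on the detection level. Without a detection level, higher genes made up 46.7% of the 4-fold differences (2885 higher, 3294 lower), with genes near background included. Higher genes made up 33.1% of the 4-fold differences as deposited, 42.2% after quantile normalization (1082 higher, 1483 lower) and 47.5% after median centring (1304 higher, 1444 lower).

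**Figure D1:**
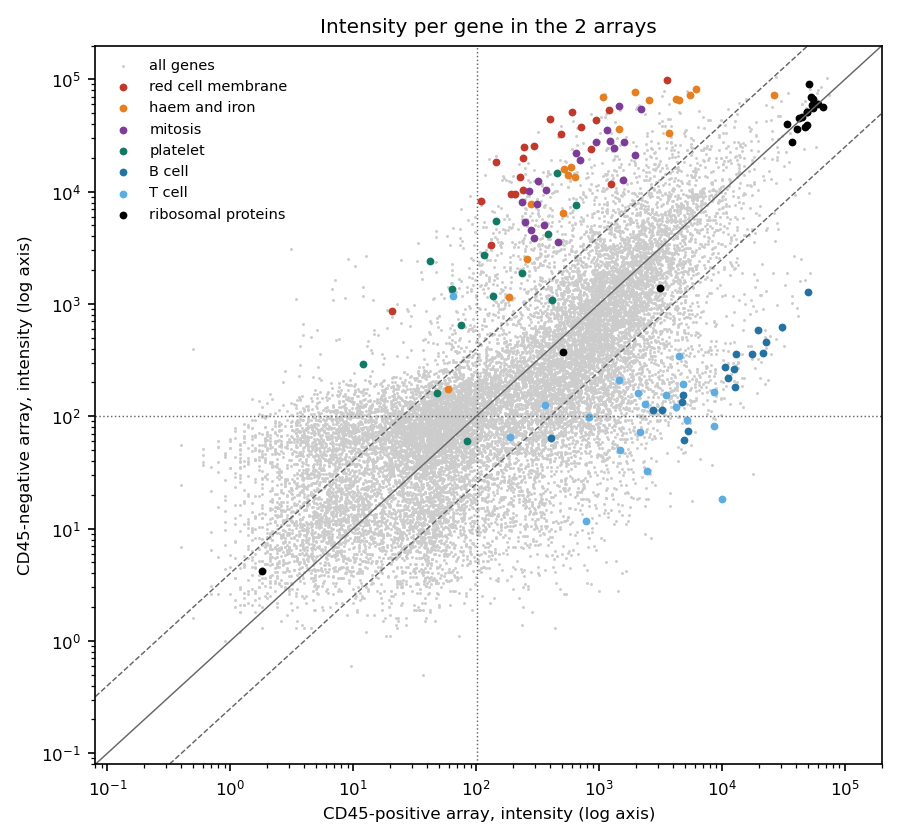
Intensity of each of 18193 genes in the CD45-negative array (vertical, log axis) against the CD45-positive array (horizontal, log axis), 1 array each, with members of 7 lists in colour. The solid line marks equal intensity, dashed lines 4-fold differences and dotted lines the detection level of 101.1. Red cell membrane genes lie above the upper dashed line, B cell genes below the lower one, and the bright ribosomal protein genes near equality.

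Genes of the red cell membrane, of haem synthesis and iron uptake and of late red cell maturation were higher in the CD45-negative cells. All 20 measured genes of the red cell membrane and its skeleton were at least 4-fold higher, with a median difference of 5.68 (51.2-fold). They included Ank1, Rhd, Epb42 (protein 4.2, 25035 against 245.2) and Dmtn (dematin, 25672 against 297.2). Of 19 measured haem synthesis and iron uptake genes, 17 were at least 4-fold higher and 0 lower, with a median of 3.98 (15.8-fold), or 4.64 without probe sets marked as cross-hybridizing. Alas2, the first enzyme of erythroid haem synthesis, had 69687 against 1082, Fech, which inserts iron into the porphyrin ring, 77605 against 1976, Uros 15960 against 520.5, and Hebp1 7823 against 278.4. The differences of Fech and Uros were 4.30 and 5.81 with the mean of probe sets. The transferrin receptor gene Tfrc (CD71) stood at 64930 against 4433, 14.6-fold higher (4.97 on the log2 scale with the mean of probe sets). All 20 measured genes of late maturation were at least 4-fold higher, with a median of 3.75. The direction of 1 of them, Map1lc3b, is uncertain, since its probe sets ran from -1.62 to 2.17. Among them Trim10 was 57.3-fold higher, Ube2l6 47.7-fold, Bpgm, which makes the haemoglobin ligand 2,3-bisphosphoglycerate, 41.4-fold, and Ube2o, a ubiquitin ligase of reticulocyte maturation, 41.2-fold.

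Erythroid regulators and globins were less uniform. Of 21 regulators measured, 14 were at least 4-fold higher and 7 were in neither class, with a median of 2.98. The highest were Sox6 (72.1-fold), Klf1 (69.7-fold), Tal1 (67.1-fold) and Gfi1b (49.2-fold), transcription factors of the erythroid lineage. Of the 7 in neither class, Myb (678 against 1909), Bcl11a (927 against 2276), Ldb1 (839 against 1600.5) and Kit, the stem cell factor receptor (84.2, under the level, against 234.9), were dimmer in the CD45-negative array. Gata2 (288 against 126.8), Bach1 (2852 against 1391) and Zbtb7a (355 against 340) were brighter, and Cd34 was under the level in both arrays. The globin list had 5 measured members, of which only Hbb-b2 passed 4-fold, with a median of 1.33. The embryonic Hbb-bh1 (329 against 119.3) and the adult Hba-a2 (611 against 243.8) did not. The embryonic Hbb-y (145.4 against 5.6) and Hba-x (105.6 against 35.5) were under the level in the CD45-positive array. Their differences of at least 0.52 and at least 0.06 against the common level do not show whether they differed by 4-fold. The bound of Hba-x is not secure, since 105.6 lies under 127, the 95th percentile of the receptor probe sets in the CD45-negative array. With a detection level set for each array, 4 globin genes were measured. With the mean of probe sets, the differences of Hbb-bh1 and Hbb-y were 0.02 and 1.44. The adult Hba-a1 was under the level in both arrays, at 16.5 and 6.2 by the only probe set named for it alone. Probe sets that carry the names of several adult globin genes were not used here. The low values of this list therefore do not show that adult globin RNA was low in the CD45-negative cells. Without probe sets marked as cross-hybridizing, the globin median was 0.52. All 4 other erythroid lists lay at percentile 100 of the random lists and the globins at 99.8. The sort for Ter119, a red cell marker, favours such percentiles.

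Cell division genes were higher in the CD45-negative cells. All 21 measured mitosis genes were at least 4-fold higher, with a median of 4.63 (24.7-fold, percentile 100 of random lists). The largest differences were those of Ube2c (39.8-fold), which targets cyclins for destruction, the spindle assembly factor Tpx2 (39.2-fold, and 2.99 on the log2 scale with the mean of probe sets), Prc1 (37.2-fold) and the mitotic kinesin Kif11 (34.5-fold). Of 22 DNA replication genes, 18 were at least 4-fold higher and 0 lower, with a median of 2.71 (6.55-fold, percentile 100). The replication licensing factor Cdc6 was 32.8-fold higher, the ribonucleotide reductase subunit Rrm2 28.3-fold, the thymidine kinase Tk1 22.4-fold, and the cyclin Ccne2 20.1-fold.

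White cell genes were lower in the CD45-negative cells across lymphoid and myeloid lists. All 18 measured B cell markers were at least 4-fold lower, with a median of -5.42 (42.9-fold). Cd22 was 70.4-fold lower, Ms4a1, which encodes CD20, 59.0-fold, the complement receptor Cr2 at least 41.7-fold, and Blnk 50.8-fold. Of 10 plasma cell genes, 7 were at least 4-fold lower. The list's median of -2.45 includes lower bounds and was -4.54 without a detection level. The antibody joining chain gene Jchain was 56.2-fold, Mzb1 25.6-fold, Irf4 at least 18.7-fold and Igha 22.1-fold lower. Of 19 T cell markers, 16 were at least 4-fold lower (median -4.19), led by Cd3d and Cd2, with the interleukin-7 receptor Il7r 52.1-fold and Thy1 at least 40.9-fold lower. Only Zap70, a T cell receptor kinase, was higher, at least 11.6-fold by its brightest probe set. Its probe sets disagreed, with differences from -3.58 to 3.54, so no direction holds for it. The same holds for Cd8a among the lower genes, whose probe sets ran from -4.19 to 1.20. Of 15 natural killer and cytotoxic genes, 14 were at least 4-fold lower (median -3.52, -4.65 without a detection level and -2.86 with the 99th percentile of the receptor probe sets as the level), among them Ccl5, Gzma, Nkg7 (104.9 against 3775) and Gzmb (at least 23.2-fold). Of 19 genes shared by most white cells, 18 were at least 4-fold lower (median -5.20), with Cd37 53.6-fold and the phosphatase Ptpn6 50.3-fold lower beside Cd48 and Ptprc. With the mean of probe sets, this list's median was -4.08, and the differences of Ptpn6 and the plasma cell gene Irf4 were -3.96 and -2.89.

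Most neutrophil, macrophage and dendritic cell markers were lower in the CD45-negative cells. Of 16 measured neutrophil genes, 10 were at least 4-fold lower and 0 higher (median -3.51, and -2.85 with the 99th percentile of the receptor probe sets as the level). Chil3 was 77.5-fold lower, the calcium-binding protein S100a9 53.4-fold, the antimicrobial peptide gene Camp 43.9-fold and Ngp 37.6-fold. Of 27 macrophage and dendritic cell genes, 17 were at least 4-fold lower and 10 were in neither class (median -2.57). Of these 10, the iron exporter Slc40a1 (3203 against 984.5) and Zbtb46 (345 against 120.8) were brighter in the CD45-negative array. Mpeg1 was 47.0-fold lower, Tyrobp 41.2-fold, and the lysozyme Lyz2 21.8-fold, and the chemokine receptor Ccr2 stood at 33.3 against 2541 (a difference of -2.70 with the mean of probe sets). With a detection level set for each array, 17 of 18 B cell, 5 of 10 plasma cell and 13 of 15 natural killer and cytotoxic genes were at least 4-fold lower. These 7 white cell lists lay at percentile 0 of the random lists. The sort on CD45 favours this outcome, so these percentiles check the labels more than they add a finding. Some bright members were above the detection level in the CD45-negative array, such as S100a9 at 778, Jchain at 485 and Lyz2 at 869, while Cd3d (18.4) and Cd2 (82.8) were under it.

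Antigen presentation genes were lower in the CD45-negative cells. Of 12 genes of the MHC class II pathway, 11 were at least 4-fold lower (median -4.85), including H2-Ob, H2-Oa (55.0-fold), H2-Ab1 (52.4-fold) and H2-DMb2 (47.1-fold). Of 10 class I pathway genes, 6 were at least 4-fold lower (median -2.48). The 4 largest differences were those of Psmb8 (25.9-fold), Psmb10 (11.6-fold), Nlrc5 (10.3-fold) and Psmb9 (6.58-fold), which are immunoproteasome subunits except for Nlrc5, a class I transactivator. Of the class I molecules themselves, H2-K1 stood at 11867 against 27665 and B2m, the shared light chain, at 55566 against 47882. Both lists lay at percentile 0 of the random lists, and whether they differ from each other was not tested.

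Megakaryocyte and platelet genes were higher in the CD45-negative cells. Of 13 measured, 10 were at least 4-fold higher and 0 lower, with a median of 3.46 (percentile 100). The platelet tubulin Tubb1 was 37.5-fold higher and the chemokine precursor Ppbp 32.6-fold (14737 against 452). Of the subunits of the von Willebrand factor receptor, Gp9 was at least 24.0-fold and Gp1bb 23.4-fold higher. The difference of Gp1bb was 3.13 with the mean of probe sets. Markers of other cells that the gates could hold were mostly not measured. Of 13 liver and liver tumour genes on the array, 3 were above the level, namely Afp at 125.5 in the CD45-positive array and Apoa2 (120.9) and Epcam (110.5) in the CD45-negative array, all close to it. That list's median was 0.13 (percentile 45.8), with 0 members past 4-fold, and -1.39 without a detection level. Of 20 stromal and endothelial genes, 7 were measured (median 0.18, percentile 64.5), and only Pecam1, which platelets and white cells also carry, passed 4-fold, at 113.1 against 1351. Eng stood at 515 against 290, Igfbp7 at 139.4 against 80.8 and Cdh5 at 13.8 against 126.4. With the mean of a gene's probe sets only 2 stromal genes were measured, Pecam1 and Stab2, with a median of -1.72. Of 11 mast cell and basophil genes on the array, 5 were measured and 0 passed 4-fold (median -0.89, percentile 13.9, and 0.71 with a detection level set for each array). They included Gata2 (288 against 126.8), Mcpt8 (4.4 against 208.8), Cma1 (104.0 against 212.7) and Cpa3 (34.4 against 187.9).

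Among ligands and receptors of the GDNF and neurotrophin families, 6 of 14 genes on the array were measured and 1 passed 4-fold. It was Artn, which encodes the neurotrophic factor artemin, with 530.5 in the CD45-negative array against 3.9, at least 5.25-fold higher. With the 99th percentile of the receptor probe sets as the level, its bound was 1.73 on the log2 scale, which is under the 4-fold threshold. Gfra2 (at least 1.74-fold higher), Nrtn (1.41-fold) and Ntrk2 (at least 1.32-fold) differed less. The list's median was 0.45, at percentile 95.1 of random lists, and 1.44 with the mean of a gene's probe sets, when only 2 members were measured, Artn and Nrtn. Of 24 measured cytokines and growth factors, 8 were at least 4-fold lower in the CD45-negative array and 0 higher (median -0.80, percentile 2.81, and -1.68 with the 99th percentile of the receptor probe sets as the level). The lower ones included Ltb, Ccl5, Il16 and the interferon gene Ifng (2.8 against 1413). Of 16 genes tied to suppression of lymphocytes, 5 were at least 4-fold lower and 0 higher (median -0.88, percentile 2.79, and -1.55 without a detection level). They were led by the phagocyte oxidase subunit Cybb (49.4-fold), the galectin Lgals1 (25.6-fold), Ctla4 (at least 6.45-fold) and Cd274, which encodes PD-L1 (6.19-fold).

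Of 18 measured genes of the TGF-beta pathway, 13 were at least 4-fold lower in the CD45-negative array and 0 higher (median -2.96, percentile 0, and -2.35 with the mean of probe sets). Smad2 (300.3 against 1127), Smad5 (87.7 against 220.0), Id1 (169.3 against 172.5), Acvrl1 (53.7 against 101.4) and the co-receptor Eng (515 against 290) were in neither class. The type II receptor gene Tgfbr2 had 104.2 against 7563 (a difference of -2.39 with the mean of probe sets), the common mediator Smad4 250 against 7220, and Id2 and Id3, which encode inhibitors of DNA binding, 173.1 against 3974 and 120.9 against 1374. Interferon-stimulated genes went both ways. Of 17 measured, 2 were at least 4-fold higher and 4 at least 4-fold lower (median 0.03, percentile 40.5, -0.01 after quantile normalization and -0.42 with the mean of probe sets). Rsad2, the antiviral protein viperin, was 21.5-fold higher at 70516 against 3276, and its probe sets gave 4.43 to 5.72. Ifi27l2a was 47.4-fold, Ifit3 30.9-fold, Mx1 at least 13.5-fold and Ifit2 4.41-fold lower.

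Glycolysis genes also went both ways, with 3 of 18 at least 4-fold higher and 7 at least 4-fold lower (median -1.59, percentile 0.51). The lactate and pyruvate carrier Slc16a1 was 28.2-fold higher, and the phosphofructokinase Pfkm 4.63-fold, and the hexokinase Hk1 stood at 11753 against 1679. The glucose carrier Slc2a1 stood at 114.3 against 2314, Pfkp at 102.7 against 2017 (a difference of -2.45 with the mean of probe sets), and the pyruvate kinase gene Pkm was 8.38-fold lower. Of 22 respiratory chain genes, 21 were in neither class (median 0.40, percentile 33.7). Ndufb5 was 5.12-fold lower, and Cox6a1 (2.55-fold) and Cox7a2 (2.21-fold) were brighter. Ribosomal protein genes had a median of 0.04 (percentile 5.34), with 0 of 18 past 4-fold. They ranged from -1.19 for Rps6 (-0.33 with the mean of probe sets) to 0.83 for Rplp0. With that mean, Rps9 moved the other way, from -0.41 to -1.13. The median of the ribosomal list was -0.29 after quantile normalization and 0.48 after median centring. The broadly expressed reference genes had a median of 0.12 (percentile 23.2, and -0.11 and 0.56 under the same scalings), with 13 of 16 in neither class. The exceptions were Tfrc, which is also an erythroid gene, Pgk1 (4.58-fold lower) and Ywhaz (4.01-fold lower), and Chmp2a was 2.34-fold higher.

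**Figure D2:**
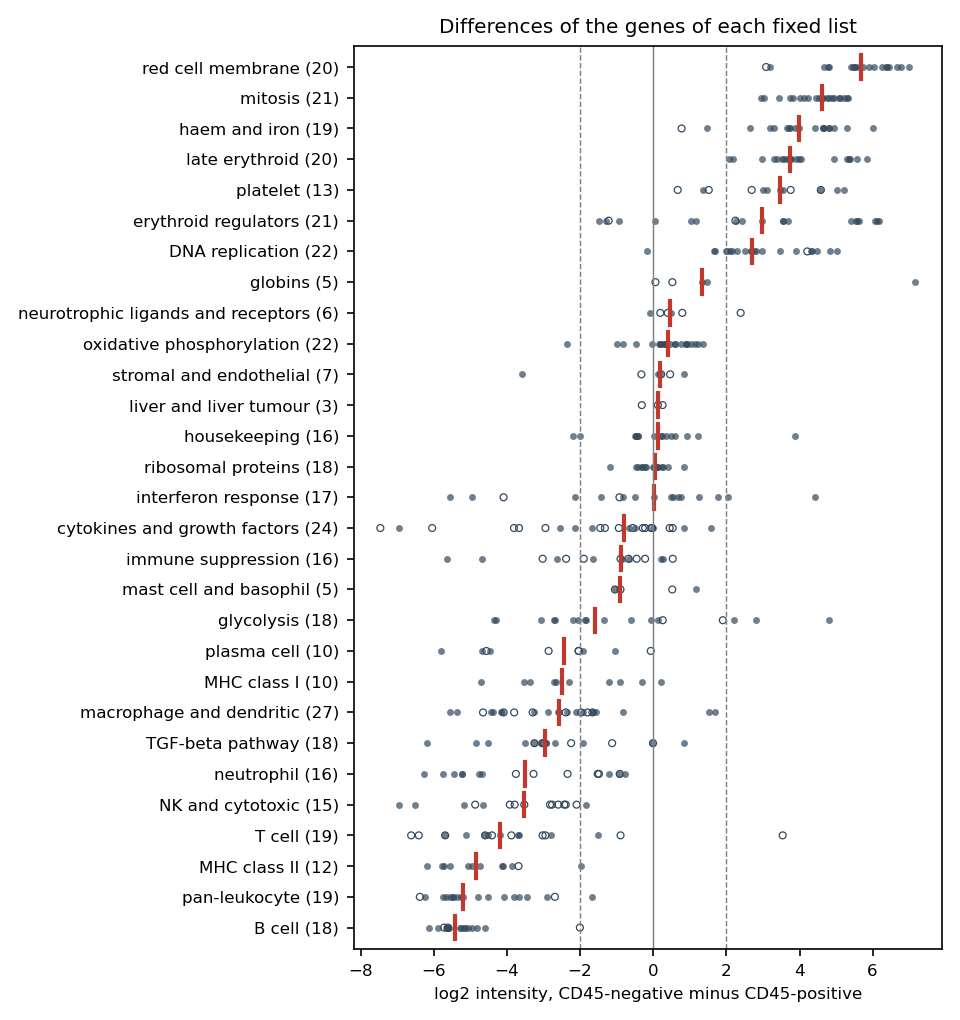
Difference in log2 intensity, CD45-negative minus CD45-positive, of each measured member of the 29 fixed lists (points), with the number measured in brackets and the median as a red bar. Open points are bounds against the common level of 101.1, for genes measured in only 1 array, and dashed lines mark 4-fold differences. The medians run from -5.42 for B cell genes to 5.68 for red cell membrane genes.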

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

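Probe sets that took no part in the comparison because they had no gene name or several also differed between the arrays. Of 3441 measured probe sets with no gene name, 148 were at least 4-fold higher and 318 at least 4-fold lower in the CD45-negative array than in the CD45-positive control, with the largest differences at 6.49 and -6.61 on the log2 scale. Of 641 measured probe sets with several gene names, 38 were at least 4-fold higher and 110 at least 4-fold lower, reaching 4.99 and -6.61. Checks for outlying samples and for differences between groups need replicates and were not made.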

How the results depend on the processing

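No paired analysis was possible because each group had 1 array, and for the same reason no replicate could be left out. Of 231 list medians recomputed under 8 alternatives, 8 moved by more than 0.83 on the log2 scale. This tolerance is the spread of single genes, so a smaller shift does not show that a median was stable. The medians of 6 lists had both signs over the settings, from -0.11 to 0.56 for housekeeping, -0.42 to 0.47 for interferon, -0.29 to 0.48 for ribosomal, -1.39 to 0.56 for liver, -1.20 to 0.71 for mast cell and -1.72 to 0.62 for stromal genes, and the globin median was 0.52 without cross-hybridizing probe sets, against 1.33. With the mean of a gene's probe sets, the pan-leukocyte median was -4.08, the stromal and endothelial -1.72 and the neurotrophic 1.44, the last 2 over 2 genes each, since fewer genes were then measured. Without a detection level, 2885 genes were at least 4-fold higher and 3294 lower, the correlation was 0.73, the spread between probe sets 1.61, and the plasma cell, natural killer and liver medians were -4.54, -4.65 and -1.39. These counts include genes near background in both arrays. The cytokine median was -1.68 with the stricter receptor percentile, under which no liver gene was measured. With a level set for each array, an alternative chosen after seeing the data, the mast cell median was 0.71, opposite in sign to -0.89. The 2-fold threshold gave 1976 higher and 3922 lower genes and the 8-fold threshold 536 and 952. Quantile normalization shared 923 of the 980 higher and 1450 of the 1979 lower genes. With the level set for each array, 12 TGF-beta genes and 6 glycolysis genes were at least 4-fold lower, against 13 and 7, and 4 glycolysis genes higher, against 3. Of 1200 recomputed differences of 152 named genes, 53 moved and 2 reversed. The reversed ones were Zap70, to -0.71 with the mean of probe sets, and Hbb-b2, to -1.09 without cross-hybridizing probe sets. A sign change counted as reversed only where the main difference was at least 2 in size on the log2 scale. Smaller differences could change sign uncounted, as did Cdh5 (-0.32 to 0.01) and Afp (-0.31 to 0.02) with a level set for each array. Artn kept its direction with the stricter percentile, but its bound of 1.73 was under the threshold. The cause of the other changes was not tested. Signal over background limits genes near intensity 101.1.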

Other observations

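The gene families in this and the next paragraph were chosen after a scan of the medians of all families with at least 8 measured genes, so their differences are selected, and they were not recomputed under other scalings. Some of their members were already counted in the fixed lists, such as E2f1, E2f2, E2f4, S100a9, Tubb1 and Kif11. All 8 measured Gimap genes, GTPases of lymphocytes, were at least 4-fold lower in the CD45-negative array (median -5.26), with Gimap4 at 409.6 against 22670. Of 8 S100a genes, 6 were at least 4-fold lower (median -4.58), and S100a10 stood at 721 against 15119. Of 9 annexins, 5 were at least 4-fold lower (median -2.47), including Anxa1 at 194.9 against 6951, while Anxa7 stood at 7525 against 1916. In the other direction, 5 of 8 E2f transcription factors were at least 4-fold higher (median 2.74), among them E2f8 (14249 against 388) and E2f7 (3020 against 120.1). Of 11 tubulin genes, 6 were at least 4-fold higher and 0 lower, and Tubb4b had 38701 against 3827. Of 30 kinesins, 12 were at least 4-fold higher and 3 lower (median 0.89), with Kif18b at 4870 against 194.2 and Kif21b at 200.5 against 3727.

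The Marchf family of membrane-bound ubiquitin ligases was split. Of 8 measured members, 4 were at least 4-fold higher in the CD45-negative array (median 2.14): Marchf8 (16329 against 251), Marchf3 (11753 against 343), Marchf2 (27307 against 1299) and Marchf5 (33019 against 3296). Marchf1, which regulates MHC class II in B and dendritic cells, stood at 93.4, under the level, against 1315 (a difference of -3.37 or below). Of 8 genes of the augmin complex, 1 was at least 4-fold higher (median 1.22). Nucleoporins (18 measured, median 0.53) had 0 members past 4-fold, and proteasome subunits (42 measured, median 0.82) had 3 higher and 3 lower. The 3 lower ones were the immunoproteasome subunits Psmb8, Psmb9 and Psmb10, already counted in the MHC class I list.

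The tests in the following paragraphs were all chosen after the results were seen. White cell transcripts were not absent from the CD45-negative array. Of 60 white cell and MHC class II genes with an intensity of at least 5000 in the CD45-positive array, 55 (91.7%, exact 95% interval 81.6% to 97.2%) were above the detection level in the CD45-negative array, and the median ratio of the 60 was 2.35% of the CD45-positive intensity. Of 80 receptor probe sets in that array, 8 (10%, exact 95% interval 4.42% to 18.8%) passed the level. The level was itself drawn from these probe sets over both arrays, and 10% is the most that its definition allows. Their share is therefore no independent background rate, and the comparison of shares does not decide on array background. For single markers, S100a9 at 778 and Lyz2 at 869 lay above the brightest receptor probe set (180.4), while Cd3d at 18.4 lay under it. A random mix of carried-over CD45-positive cells as the only source should give all white cell classes a like ratio. This holds only where intensity rises in proportion to RNA, and saturation in these arrays is not settled. The median log2 ratios were -5.62 for 12 B cell, -6.06 for 4 T cell, -5.35 for 6 neutrophil and -4.42 for 6 macrophage genes, and 0.01% of 10000 random regroupings of these 28 genes gave a gap between medians as large as the observed 1.64.

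That regrouping was the last of 3 versions of the test. The gap was first computed without the detection level, at 1.84, and set against 2 SDs between probe sets (1.67), which counted against a random mix. It was then recomputed with dim values set to the level, which could only shrink it because 3 of the 4 T cell genes lay under the level, and at 1.64 it left the question open. Since that SD describes single genes and not medians of lists, random regroupings took its place, and without the level 0 of the 10000 gave a gap as large. Genes of a list are not independent, an uneven carry-over of some cell types stays open, and transcription in the CD45-negative cells themselves was not tested.

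Among 289 genes at 5000 or more in the CD45-positive array and at least 4-fold lower in the other, 15 were under the level in the CD45-negative array. They included Ltb (30.7 against 17781), Cd3d (18.4 against 9915), Arhgap30 (36.6 against 8308), Il16 (41.7 against 6660) and Cd83 (17.6 against 5726). Of 118 such genes at 10000 or more, 1 was under the level, namely Ltb. At the median ratio of 2.35%, a gene near 5000 would itself lie close to the level, so its place under it shows little. Conversely, all 67 erythroid genes with at least 5000 in the CD45-negative array were above the level in the CD45-positive array, at a median of 3.58% of their intensity.

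Artn was measured in the CD45-negative array only, at 530.5. Background of that array is argued against as its source, since 0 of 80 receptor probe sets reached it (exact 95% interval up to 4.51%) and the brightest stood at 180.4. Signal from a transcript other than Artn cannot be told apart from Artn itself, because only 1 probe set carries that name.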
